A study of Mus musculus with 7 samples.

How the data were processed

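The series profiled RNA of primary tumours from BALB/c mice that carried 4T1 mammary carcinoma cells. Per the labels, the groups were saline (3 libraries), small extracellular vesicles of DMSO-treated 4T1 cells (Cont sEV, 1 library) and vesicles of nocodazole-treated, therapy-induced senescent 4T1 cells (TIS sEV, 3 libraries). The labels number the replicates but do not state that they are separate animals, so every p-value measures only the spread between these samples, which may be technical.

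The authors deposited 1 table of TPM values (transcript abundance corrected for length and scaled to a fixed total per library) with 55487 genes and 7 libraries. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.6, Salmon 1.4.0 and DESeq2 1.28.0, with genome build GRCm38.p6. The transcript annotation and the summing of transcripts to genes are not given in the sources used here. Each deposited TPM column summed to 1000000 over all entries, ribosomal, mitochondrial and pseudogene entries included. TPM keeps no depth, so the depth of each library is unknown and no counting interval is given. A library rich in 1 RNA class has lower TPM for all its other genes.

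The saline columns carry the words and numbers of the labels. The vesicle columns carry abbreviations, CE and NcE, each with a replicate number. CE was read as the control vesicles and NcE as the nocodazole vesicles, since the labels' protocols derive the TIS vesicles from nocodazole-treated cells and since the numbers of columns, 1 and 3, match those of the labelled libraries. This reading is not spelled out in the labels, and every comparison with a vesicle group rests on it. All columns were mapped.

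Gene types, symbols and coordinates came from the GENCODE M21 annotation of GRCm38. Of the 55487 gene identifiers, 55227 were found there with the version dropped, 54435 with the same version, and 55141 had a symbol. Genes with near-identical copies, such as the U3, U1 and histone genes, share reads that the quantification could split, and their values are uncertain.

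The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with no further scaling. Genes with at least 1 TPM in at least 3 of the 7 libraries were tested, which left 12058. One fit held 1 mean for each of the 3 groups, with 4 residual degrees of freedom, so the lone Cont sEV tumour was assumed to vary like the others. Two-sided moderated tests used the intensity trend, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A log2 difference on this scale understates the change of low genes. The prior degrees of freedom were infinite, so each gene took the spread fitted for its expression level and its own spread had no weight. With TPM divided by median-of-ratios size factors, they were 3.04, and the median residual SD fell from 0.62 to 0.30 on the log2 scale.

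The median gene differed by -0.62 (log2) between TIS sEV and saline, by -0.29 between TIS sEV and Cont sEV and by -0.33 between Cont sEV and saline. Size factors brought these medians to -0.0037, -0.0042 and -0.0023. Values of gene lists and their members are therefore given relative to the median gene, that is, the fitted log2 difference minus the median over all tested genes. Values of other genes are the fitted differences. The limma p-value of a gene tests its fitted difference against 0, also where a value relative to the median gene is printed.

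A total of 28 gene lists (cell types, pathways and tissues adjacent to the tumour) were fixed before the data were examined, and 25 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Camera compares a list with all other genes. Fry's directional test asks whether the genes of a list move, on balance, one way. It was run on the fitted differences, with the shift of the median gene left in.

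Named genes followed a rule fixed before the data were examined. It took genes with an adjusted p under 0.05, a symbol that is no predicted or clone name, at least 5 TPM in the higher group and groups that did not overlap. The 12 largest differences in each direction were named for TIS sEV against saline, and 6 for each comparison with Cont sEV. Places left open went to genes with the smallest unadjusted p that met the other conditions, and these are named as not passing. Up to 4 members of each list and 9 single genes were also fixed.

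Both the gene test and the list test were tested on simulated data with the spread of these libraries and with genes drawn independently of each other. In simulations of TIS sEV against saline over 12058 genes, 28% of 100 genes changed by 2 log2 units and 86% of 100 genes changed by 4 were called, with 8 false calls among 11858 unchanged genes. For Cont sEV against saline, 4% and 64% were called, with 1 false call. These counts of false calls hold for independent genes only. Unchanged groups simulated with genes related as in the libraries gave calls in 40 of 100 draws for TIS sEV against saline (mean 227, highest 8763). For Cont sEV against saline they gave calls in 42 of 100 draws (mean 293, highest 9919). A list shifted by 1 log2 unit, that of T cells, was recovered at an adjusted p of 3.69e-07, and 0 of 24 other lists were called by camera at the preset correlation. In the libraries the estimated inter-gene correlation of that list was 0.862. The simulation with independent genes therefore cannot show how often camera calls lists falsely in these data.

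Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, size factors, quantile normalization, 6 lists left out with TPM rescaled, robust and untrended moderation, array weights, the replicate number as a block, each saline and TIS sEV library left out, a joint control group, the 6 saline and TIS sEV libraries alone, and other thresholds. Added after seeing the data were nuclear coding genes only (with immunoglobulin and T-cell receptor genes), the same with size factors, size factors without TIS sEV replicate 2, and each gene's own spread without moderation. The array weights did not converge and gave TIS sEV replicate 3 a weight of 72.3.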

Results

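Tumours grew in mammary fat pads of BALB/c mice from 4T1 cells, a mouse mammary carcinoma line, carrying luciferase. At about 150 mm3 they received 6 injections of 50 µl of saline, control vesicles (Cont sEV) or vesicles of therapy-induced senescent cells (TIS sEV), 1 every other day, and the tumours carry the label day 12. The vesicle donors were 4T1 cells treated for 72 h with DMSO or with 100 ng/ml nocodazole, a drug that blocks microtubule assembly, and then released for 72 h. The series asks how vesicles of senescent tumour cells affect growing tumours. Expression was given as TPM for 3 saline, 1 Cont sEV and 3 TIS sEV libraries, with unknown depth.

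The RNA make-up of TIS sEV replicate 2 differed from that of the other 6 libraries. Nuclear ribosomal RNA genes took 22.9% of its TPM, against 0.807% to 2.40% in the others. Nuclear protein-coding genes took 28.6%, against 56.8% to 74.7%. It had 8909 genes at 1 TPM or more, against 11378 to 12328, and its 20 highest genes took 67.8% of the total. Across genes, which are not independent replicates, its log2(TPM + 1) values correlated with those of the others at r = 0.842 to 0.910, and the other 6 libraries among themselves at 0.930 to 0.970. No pair of libraries held identical values. The first principal component held 73.4% of the variance and set TIS sEV replicate 2 apart.

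**Figure D1:**
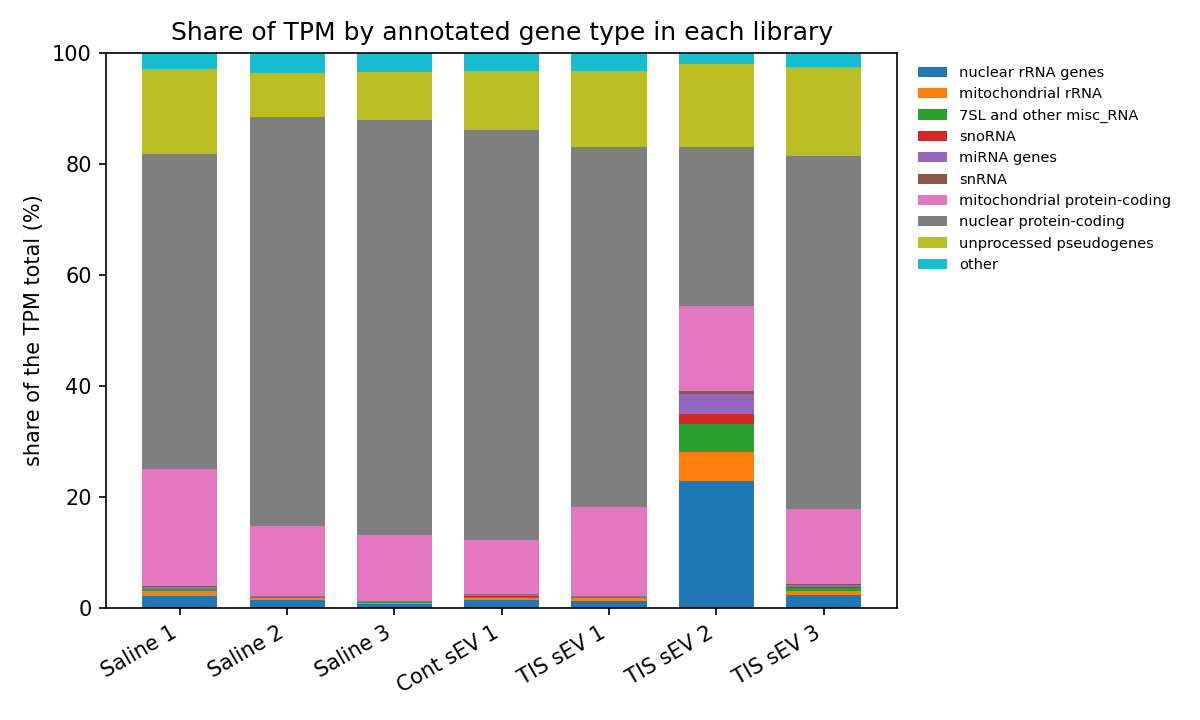
Share of the TPM total (%, vertical axis) of each annotated gene type in the 7 libraries. Nuclear ribosomal RNA genes took 22.9% in TIS sEV replicate 2 and 2.40% or less in every other library.

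In tumours given TIS sEV, antibody genes, a chemokine and a pair of genes for mitochondrial proteins were higher than in saline tumours. Igkc, the constant region of the kappa light chain (chromosome 6, 70726435 to 70726966, GRCm38), averaged 69.1 ± 47.0 TPM (SD, n = 3) with TIS sEV and 3.50 ± 3.15 with saline, a log2 difference of 3.91 (SE 0.66, limma adjusted p = 5.03e-06). Ighg1, the constant region of an immunoglobulin G heavy chain (chromosome 12, 113325240 to 113330523), rose by 3.57 (SE 0.61, adjusted p = 8.04e-06). Chchd10, a protein of the mitochondrial intermembrane space (chromosome 10, 75933130 to 75937747), went from 6.38 ± 0.736 to 55.8 ± 10.3 TPM (SD, n = 3), a log2 difference of 2.93 (SE 0.66, adjusted p = 0.00415). Ccl8, a chemokine that attracts monocytes (chromosome 11, 82115185 to 82116799), rose by 2.31 (SE 0.55, adjusted p = 0.00963), from 555 ± 594 to 1898 ± 189 TPM (SD, n = 3). The mitochondrially encoded mt-Nd6, a subunit of respiratory complex I, rose by 2.75 (SE 0.56, adjusted p = 0.000581), and by 1.86 without TIS sEV replicate 2 and 3.64 without TIS sEV replicate 1. It was at 470, 5551 and 1590 TPM in the TIS sEV libraries and at 434, 206 and 151 TPM in the saline libraries. With size factors, which remove the shift of the median gene, the log2 differences were 4.59 for Igkc, 4.14 for Ighg1, 3.66 for Chchd10, 3.10 for Ccl8 and 3.55 for mt-Nd6 (SE 0.52 to 1.29), and none passed (adjusted p of 0.321 to 0.338). Igkc did not pass with quantile normalization (0.322) or no filter (0.638) either. The difference of Igkc was 4.51 without TIS sEV replicate 1, and that of Ccl8 was 3.16 without saline replicate 2. Calls were also lost without 1 library. These were Ighg1 without saline replicate 3 (adjusted p = 0.0570), Chchd10 without saline replicates 1, 2 or 3 (0.0851, 0.197 and 0.272) or TIS sEV replicate 3 (0.108), mt-Nd6 without saline replicates 2 or 3 (0.0910 and 0.3001), and Ccl8 without saline replicates 1 or 3 (0.457 and 0.879) or TIS sEV replicate 3 (0.109).

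Spp1, Dmp1, Col18a1, Fn1 and Plac9a were lower in the TIS sEV tumours. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), averaged 4370 ± 810 TPM (SD, n = 3) with saline and 1730 ± 1687 with TIS sEV, a log2 difference of -2.56 (SE 0.52, adjusted p = 0.000581). Dmp1, a phosphoprotein of mineralised matrix on the same chromosome (104202613 to 104214102), fell by 2.62 (SE 0.66, adjusted p = 0.0181). Col18a1, a basement membrane collagen, fell by 2.44 (SE 0.65, adjusted p = 0.0390), and Fn1, which encodes fibronectin, by 2.13 (SE 0.58, adjusted p = 0.0467). Plac9a fell by 1.99 (SE 0.52, adjusted p = 0.0328). Without TIS sEV replicate 2, Spp1 differed by -0.84 (adjusted p = 0.206), Col18a1 by -1.20 (adjusted p = 0.128) and Fn1 by -0.71 (adjusted p = 0.513), so these 3 calls were lost. That library held them at 66.7, 0.996 and 27.2 TPM. The highest TIS sEV and lowest saline values nearly met for Spp1 (3439 and 3450 TPM), Col18a1 (27.5 and 29.0) and Fn1 (578 and 604). They lay further apart for Dmp1 (8.32 and 18.7) and Plac9a (1.41 and 4.28). Leaving out TIS sEV replicate 1 gave -3.16, -3.11 and -2.79 for Spp1, Col18a1 and Fn1, leaving out TIS sEV replicate 3 gave -3.68 for Spp1 and -2.89 for Fn1, and leaving out saline replicate 3 gave -1.87 for Dmp1. With size factors the differences were -1.77 for Spp1, -1.96 for Dmp1, -1.83 for Col18a1, -1.34 for Fn1 and -1.69 for Plac9a, and none passed (adjusted p of 0.338 to 0.397). Without saline replicates 1, 2 or 3, adjusted p was 0.0695, 0.158 and 0.879 for Dmp1, 0.0768, 0.866 and 0.879 for Col18a1, 0.139, 0.866 and 0.879 for Fn1 and 0.117, 0.338 and 0.879 for Plac9a, and that of Spp1 was 0.118 and 0.202 without saline replicates 2 and 3. Leaving out TIS sEV replicate 3 gave 0.0616 for Dmp1, 0.0501 for Col18a1 and 0.126 for Plac9a.

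The small nucleolar RNA Rnu3b3, a copy of the U3 RNA that guides ribosomal RNA processing, was listed at 0 in every saline library and at 57.6, 411 and 282 TPM with TIS sEV. Its near-identical copies make the value uncertain. Further genes named by rank separated the groups without passing the adjusted threshold. Values were higher for mt-Tm, a mitochondrial tRNA (2.25), Igf1, a growth factor (1.77), Cbr2 and Cbr3, carbonyl reductases (1.99 and 1.69), Fam213b (1.72) and Crabp2, a retinoic acid binding protein (5.31 ± 3.77 against 1.30 ± 1.09 TPM, SD, n = 3), with adjusted p of 0.0989 to 0.389. Values were lower for Cd9, a tetraspanin (-2.14), Wls, a carrier of secreted Wnt proteins (-2.25), Npnt, a matrix protein (-2.24), Gja1, a gap junction protein (-2.19), Amigo2 (-2.12), Pcmtd2 (-1.75) and Nt5e, an enzyme that forms adenosine outside cells (-1.96), with adjusted p of 0.0553 to 0.208.

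Altogether 62 of 12058 genes passed, 42 higher and 20 lower, and 1245 had an unadjusted p under 0.05. Of the 62, 27 were nuclear protein-coding genes, 25 small non-coding RNAs, 5 pseudogenes, 2 immunoglobulin genes, 1 a mitochondrial protein gene and 2 of other types. The groups did not overlap for 30 of the 62, and for 14.3% of all tested genes, where chance gives 10%. With size factors limma called 0 genes (lowest adjusted p = 0.231) and 1781 had an unadjusted p under 0.05, and quantile normalization also gave 0 (1755). All 62 kept their sign there, and 36 had an unadjusted p under 0.05. Leaving out 1 library gave 14 calls without saline replicate 2, 7 without saline replicate 3, 353 without TIS sEV replicate 1, 105 without TIS sEV replicate 2 and 35 without TIS sEV replicate 3. Without TIS sEV replicate 1 the balance turned, with 102 higher and 251 lower. In every other fit without 1 library, more calls were higher than lower. Among the 11 named genes that passed, Rnu3b3 and Igkc passed whichever of these 6 libraries was left out, and the other 9 lost the call at least once.

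**Figure D2:**
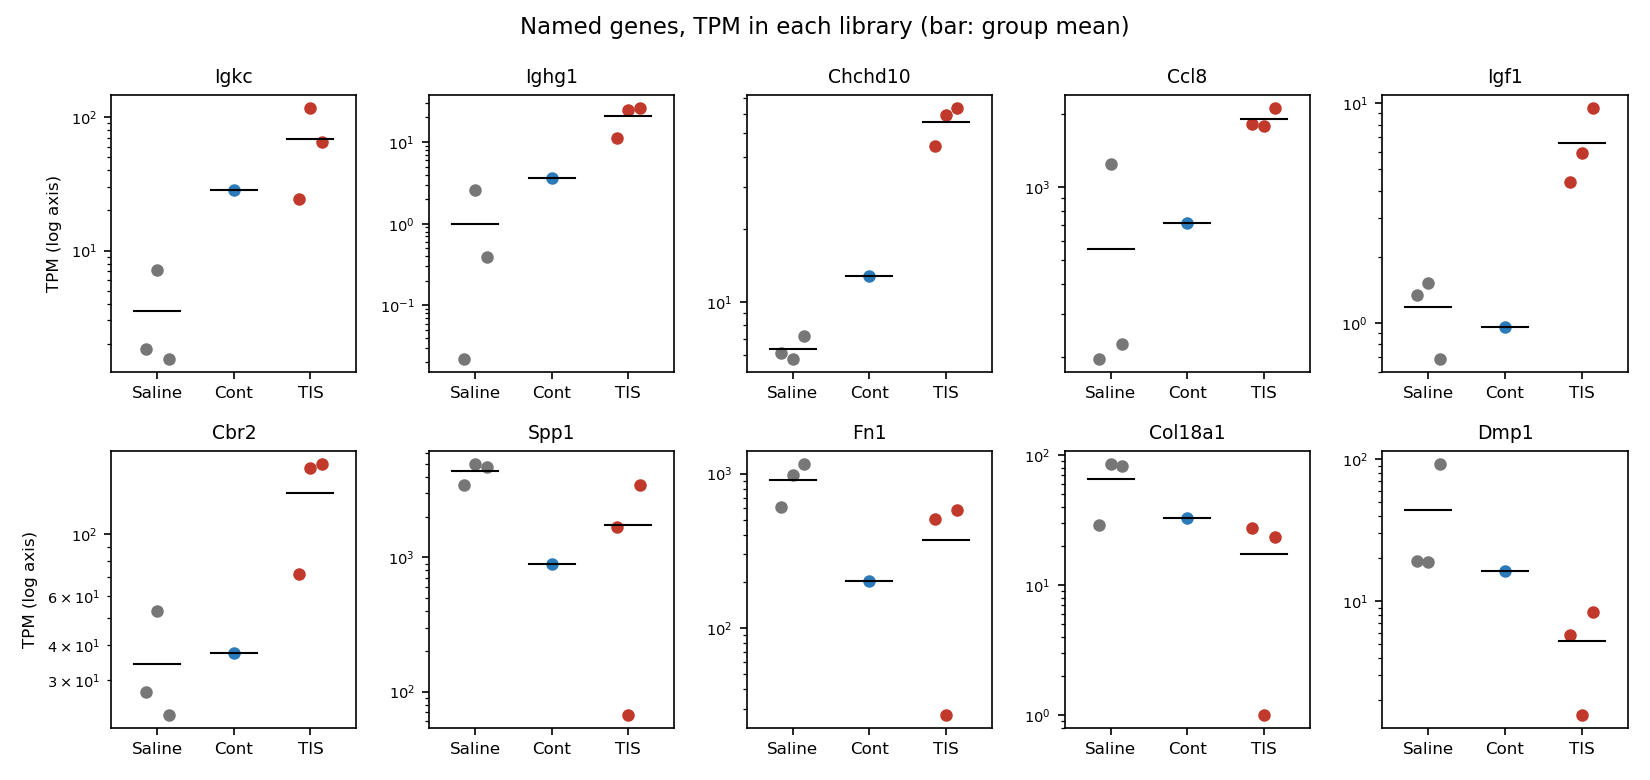
TPM (log axis) of 10 named genes in each library (points) by group, with the group mean as a bar. Igkc lay between 24.4 and 118 TPM in the TIS sEV libraries and at 7.13 or below in the saline libraries, while Igf1 and Cbr2 did not pass the adjusted threshold.

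Relative to the median gene, the lists of T cells, dendritic cells, B and plasma cells and mitochondrially encoded genes were higher in TIS sEV than in saline tumours. That of hypoxia and glycolysis was lower. The median gene itself differed by -0.62. All 4 tested members of the B and plasma cell list lay above the median gene (list median 2.49, camera adjusted p = 1.92e-28, and adjusted p = 0.0984 with an estimated correlation). Igkc and Jchain, the joining chain of secreted antibodies (2.35, SE 0.42, adjusted p = 0.0124), rose, while Ighm (2.63) and Iglc2 (1.96) did not pass. All 4 passed when adjusted over the list alone. The list median was 1.57 without TIS sEV replicate 2 (adjusted p = 1.19e-14, and adjusted p = 0.506 with an estimated correlation). Jchain was at 1.59 without TIS sEV replicate 2 (adjusted p = 0.0126). It did not pass over all genes without saline replicates 1, 2 or 3 (adjusted p = 0.181, 0.231 and 0.879). The 11 tested T cell genes, among them Trbc2 of the T-cell receptor (1.51, SE 0.65) and the kinase Zap70 (0.96, SE 0.41), had a median of 0.73 (adjusted p = 0.000627, and adjusted p = 0.880 with an estimated correlation). Of 16 dendritic cell genes 8 were tested, led by the chemokine Ccl5 (1.72, SE 0.65), and 7 lay above the median gene. The list median was 0.60, with a camera adjusted p of 0.00777 and an adjusted p = 0.880 with an estimated correlation. Mean TPM with TIS sEV was below that with saline for Itgax (1.24 against 2.78) and Cd86 (2.67 against 3.65). It was above it for the chemokines Ccl17 (3.47 against 1.91) and Ccl22 (0.93 against 0.64). No member of either list passed, over all genes or adjusted over the list alone. Neither list was called without TIS sEV replicate 3 (adjusted p = 0.0668 for T cells and 0.119 for dendritic cells).

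The hypoxia and glycolysis list lay below the median gene by a median of -0.53, with 15 of 17 members below it. Ldha, the lactate dehydrogenase A subunit, differed by -0.88 (SE 0.55), Car9, a carbonic anhydrase induced by low oxygen, by -1.04 (SE 0.63) and the glucose transporter Slc2a1 by -0.98 (SE 0.64). Its adjusted p was 0.00389, with an adjusted p = 0.880 with an estimated correlation and 0 members passing adjusted over the list alone. The 13 mitochondrially encoded genes had a median of 0.50 (adjusted p = 0.000710, and adjusted p = 0.880 with an estimated correlation). Here mt-Nd6 passed over all genes, and adjusted over the list alone 1 member passed as higher and 1, mt-Atp8 (-0.66), a subunit of ATP synthase, as lower. Size factors ended the calls of hypoxia and glycolysis (median -0.35, adjusted p = 0.0585) and of the mitochondrial list (median 0.68, adjusted p = 0.0838). The mitochondrial list was not called without TIS sEV replicate 2 (median 0.34, adjusted p = 0.104) or saline replicate 3 (0.23, adjusted p = 0.0663), and its median was 1.03 without saline replicate 1 (adjusted p = 1.57e-09, and adjusted p = 0.162 with an estimated correlation). Hypoxia and glycolysis was not called without saline replicate 1 (adjusted p = 0.0776).

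The other 20 lists did not pass against saline (adjusted p of 0.0711 to 0.875). Their medians relative to the median gene were 0.58 for cytotoxic and NK cells, 0.46 for immune checkpoints and regulatory T cells, 0.41 for endothelial cells, 0.59 for keratinocytes and hair follicle, 0.27 for MHC class II, 0.27 for monocytes and macrophages, 0.27 for fibroblasts and extracellular matrix, with 12 of 19 members above the median gene, 0.23 for oxidative phosphorylation, 0.19 for senescence-associated secretory factors and 0.17 for senescence and p53 targets. The medians were -0.38 for epithelial tumour cells, -0.30 for skeletal muscle, -0.29 for proliferation, -0.29 for MHC class I, -0.28 for TGF-beta targets, -0.26 for epithelial-mesenchymal transition, -0.17 for immediate early and heat shock genes, -0.16 for interferon-stimulated genes, -0.15 for erythroid genes and -0.012 for neutrophils, which turned to 0.095 with size factors. Within these lists Spp1 and Fn1 passed, also adjusted over the list alone, and no other member did in limma. For MHC class I the mean was 0.014 with a negative median and test, and for neutrophils the mean (0.15) and the test were positive with a negative median. Adipocyte, milk protein and lymph node stroma genes had too few tested members (2, 0 and 0). Size factors gained 1 call, that of oxidative phosphorylation as higher (median 0.40, adjusted p = 0.000750, and adjusted p = 0.795 with an estimated correlation). Leaving out TIS sEV replicate 2, the library rich in ribosomal RNA, gave 13 called lists in place of 5. The median of MHC class I turned to 0.42 there and was called as higher (adjusted p = 0.000226). Senescence-associated secretory factors (0.60, adjusted p = 9.87e-09), MHC class II (0.75, 6.90e-06), cytotoxic and NK cells (0.75, 0.000111), endothelial cells (0.59, 0.000710), immune checkpoints (0.57, 0.00244), fibroblasts (0.43, 0.00369) and oxidative phosphorylation (0.32, 0.0317) were also called as higher, and erythroid genes (-0.61, 0.000874) as lower. The adjusted p of these 9 lists was 0.506 to 0.856 with an estimated correlation. Without saline replicate 1, 8 lists were called, among them secretory factors (0.32, adjusted p = 0.0322), neutrophils (0.69, 0.00395) and fibroblasts (0.65, 0.00727) as higher and proliferation (-0.43, 0.0465) as lower. Without saline replicate 2, 11 lists were called, among them monocytes and macrophages (0.50), cytotoxic and NK cells (0.61), immune checkpoints (0.43) and endothelial cells (0.48) as higher and interferon-stimulated genes (-0.31) and skeletal muscle (-0.76) as lower, with adjusted p of 0.0149 to 0.0465. Calls were also gained by MHC class II (0.61, adjusted p = 0.00347) and cytotoxic and NK cells (0.50, 0.0353) without saline replicate 3, by monocytes and macrophages (0.86, 0.0221) without TIS sEV replicate 1 and by erythroid genes (-0.71, 0.0284) without TIS sEV replicate 3. Each call gained without these 5 other libraries had an adjusted p of 0.901 or more with an estimated correlation. Other medians turned direction without being called. That of keratinocytes and hair follicle, at 1.62 in TIS sEV replicate 2, was -0.012 without that library. Leaving out TIS sEV replicate 1 gave -0.37 for secretory factors, 0.79 for erythroid genes and 0.037 for neutrophils, and leaving out TIS sEV replicate 3 gave -0.10 for MHC class II, -0.021 for monocytes and macrophages and -0.0042 for endothelial cells. Monocytes and macrophages were at -0.036 without saline replicate 1, erythroid genes at 0.23 without saline replicate 2, and fibroblasts at -0.041, skeletal muscle at 0.21 and interferon-stimulated genes at 0.023 without saline replicate 3. In fry 0 lists passed, with a lowest adjusted p of 0.809 and 1 list at an unadjusted p under 0.05.

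The cell cycle inhibitor Cdkn1a, a gene raised in senescent cells, differed from saline by 0.50 relative to the median gene (SE 0.65), at 24.0 ± 12.9 against 23.8 ± 3.67 TPM (SD, n = 3), and did not pass. Cdkn2a and Cdkn2b stayed under 1 TPM in every library and were not tested. The cytokine Il6 (1.19, SE 0.41), the proliferation marker Mki67 (-0.54, SE 0.64), the checkpoint ligand Cd274 (0.24, SE 0.63), the epithelial marker Epcam (-0.62, SE 0.64), the leukocyte marker Ptprc (-0.29, SE 0.53) and the macrophage marker Adgre1 (-0.077, SE 0.52) did not pass either (adjusted p of 0.476 to 0.709). The fitted difference of Il6, to which its p belongs, was 0.57.

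The comparison of TIS sEV with Cont sEV asks what the senescent origin of the vesicles adds, and it rests on 1 Cont sEV tumour. Wfdc18, a whey acidic protein family member (chromosome 11, 83709015 to 83711348, GRCm38), was at 28.7 TPM with Cont sEV and 3.17 ± 4.06 (SD, n = 3) with TIS sEV, a log2 difference of -3.28 (SE 0.70, adjusted p = 0.00296). The same library held the milk protein genes Csn2 and Csn3, which encode caseins, at 17.3 and 12.8 TPM and the basal keratin Krt5 at 1.41, while the highest values in the other libraries were 0.345, 0.598 and 0.428. These 3 genes did not meet the filter and were not tested. The histone gene Hist1h2ah fell by 2.23 (SE 0.49, adjusted p = 0.00411), with close copies that make it uncertain. Rnu1b1, a spliceosomal U1 RNA copy, and the small nucleolar RNA Snora21 passed as higher (adjusted p = 0.0126 and 0.0459). They were listed at 0 with Cont sEV, and the TIS sEV libraries held 10.6, 18.3 and 4.66 TPM of Rnu1b1 and 3.56, 30.4 and 3.78 of Snora21. Without saline replicates 2 or 3, which enter through the spread, adjusted p was 0.131 and 0.0987 for Wfdc18, 0.346 and 0.297 for Rnu1b1 and 0.370 and 0.558 for Snora21, and without replicate 3 it was 0.0889 for Hist1h2ah. Wfdc18 differed by -4.04 without TIS sEV replicate 2. With size factors Wfdc18 differed by -2.84 and Hist1h2ah by -2.22, and none of the 4 passed (adjusted p = 0.903). Snora21 also lost the call without saline replicate 1 (0.177), and without TIS sEV replicate 3 both Snora21 (0.0743) and Wfdc18 (0.129) did.

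Named by rank without passing were the small RNAs Mir2137, Snord15a, Rmrp and Scarna13 as higher, Mir2137 and Scarna13 being listed at 0 with Cont sEV. As lower came Ltf, which encodes lactoferrin (-2.70), Plac9a (-2.53), Smim22 (-2.68) and Fam178b (-2.54), and the adjusted p of the 8 genes ran from 0.0846 to 0.192. In all, 27 genes passed, 17 higher and 10 lower, of which 20 were small non-coding RNAs and 2 nuclear protein-coding genes, and 209 had an unadjusted p under 0.05. The Cont sEV library lay outside the TIS sEV range for 14 of the 27 and for 24.6% of all tested genes, where chance gives 50%. With size factors and with quantile normalization 1 gene passed, as higher (586 and 582 at an unadjusted p under 0.05). Leaving out saline replicates 2 or 3 gave 12 and 10 calls, and leaving out TIS sEV replicates 1, 2 or 3 gave 62, 103 and 16. Each of the 4 named genes that passed lost the call without at least 1 library.

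Among the lists, proliferation, antigen presentation, interferon-stimulated and epithelial genes were lower in TIS sEV tumours than in the Cont sEV tumour. The proliferation list had a median of -0.98 relative to the median gene, with 29 of 30 members below it, including the replication licensing factors Mcm3 (-1.68, SE 0.90) and Mcm2 (-1.47, SE 0.93). MHC class I had a median of -0.90, with the peptide transporter gene Tap1 at -1.36 (SE 0.91), and without TIS sEV replicate 2 these were -0.28 (adjusted p = 0.0181) and -0.61. MHC class II had a median of -0.76 (-1.16 without TIS sEV replicate 3 and -0.16, not called, without TIS sEV replicate 2), and interferon-stimulated genes -0.64, with Bst2, an antiviral membrane protein, at -1.37 (SE 0.82). Epithelial tumour cells had a median of -0.82, with the keratin Krt7 at -1.85 (SE 0.92), against the 1 library with Csn2 at 17.3 TPM, skeletal muscle -1.19 and oxidative phosphorylation -0.34. Of the 15 skeletal muscle genes, 4 were tested. Relative to the saline mean and the median gene, their median was 0.80 in the Cont sEV library, inside the saline range of -0.90 to 1.09. Camera adjusted p of these 7 lists ran from 2.18e-11 to 0.0268, and none was called with an estimated correlation (adjusted p of 0.851 to 0.910). Higher lists were neutrophils (1.27), the mitochondrially encoded genes (1.00, and 0.46 without TIS sEV replicate 2), T cells (0.73), cytotoxic and NK cells (0.61) and fibroblasts and extracellular matrix (0.33), with adjusted p of 2.01e-09 to 0.0268. With an estimated correlation the lowest adjusted p of the 12 was 0.851, and 0.519 or more without TIS sEV replicate 2. In fry 0 lists passed, with a lowest adjusted p of 0.963 and 0 lists at an unadjusted p under 0.05.

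Members of the neutrophil list differed in direction: Ltf was at -2.41 (SE 0.73) relative to the median gene and passed as lower adjusted over the list alone, as Lcn2, a granule protein that binds bacterial iron carriers, did as higher (2.58, SE 0.83). No other list had a member that passed adjusted over the list alone. Size factors ended the calls of MHC class II (median -0.65, adjusted p = 0.143), cytotoxic and NK cells (0.49, adjusted p = 0.0839) and fibroblasts (0.38, adjusted p = 0.131). Leaving out TIS sEV replicate 2 ended that of MHC class II (median -0.16, adjusted p = 0.433). Without TIS sEV replicate 1 the calls of cytotoxic and NK cells (adjusted p = 0.0907), fibroblasts (0.0614) and oxidative phosphorylation (0.132) ended. Without TIS sEV replicate 3 those of T cells (0.0766) and cytotoxic and NK cells (0.191) did, and the fibroblast median was -0.020 (0.420). The lists of senescence-associated secretory factors (0.11, adjusted p = 0.514) and of senescence and p53 targets (0.14, adjusted p = 0.355) did not pass. Leaving out TIS sEV replicate 2 gave a median of 0.49 for the secretory factors, called as higher (adjusted p = 1.38e-06, and adjusted p = 0.519 with an estimated correlation). B and plasma cells (0.56, adjusted p = 0.0656) were called without TIS sEV replicate 1 (1.33, adjusted p = 2.09e-05) or 3 (0.71, 0.0352), erythroid genes (0.28) without replicate 1 (1.25, 0.00335) and dendritic cells (-0.26) as lower without replicate 3 (-0.43, 0.0363). The adjusted p of these calls was 0.748 to 0.914 with an estimated correlation. Leaving out TIS sEV replicate 2 turned B and plasma cells to -0.37 (adjusted p = 0.172) and erythroid genes to -0.19 (0.482), which were at -0.27 without replicate 3. The secretory factors were at -0.34 without replicate 1 and at -0.0041 without replicate 3, and none of these was called. Median and mean differed in sign for epithelial-mesenchymal transition (0.017 and -0.040, test lower) and for monocytes and macrophages (-0.0063 and 0.086, test higher), which did not pass. Without TIS sEV replicate 1 these medians were -0.20 and 0.35, and with size factors that of monocytes and macrophages was 0.020. None of the 7 tested single genes passed. Relative to the median gene, Cdkn1a was at 0.10 (SE 0.92), Il6 at 0.90 (SE 0.58), Mki67 at -0.92 (SE 0.91) and Epcam at -1.20 (SE 0.90). Cd274 (0.11), Adgre1 (0.044) and Ptprc (0.028) lay near the median gene, with Ptprc at -0.10 with size factors and Adgre1 at -0.039 with quantile normalization.

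The comparison of Cont sEV with saline gives the change with vesicles of cells that were not treated with nocodazole, again with 1 tumour on that side. Wfdc18 was at 28.7 TPM with Cont sEV and 0.672 ± 0.345 (SD, n = 3) with saline, a log2 difference of 4.17 (SE 0.70, adjusted p = 6.09e-06). In the same Cont sEV library the casein genes Csn2 and Csn3, which were not tested, were at 17.3 and 12.8 TPM. The lactoferrin gene Ltf rose by 3.13 (SE 0.73, adjusted p = 0.00986), the small membrane protein gene Smim22 by 3.11 (SE 0.79, adjusted p = 0.0392) and Hist1h2ah by 2.10 (SE 0.49, adjusted p = 0.0105). The mitochondrially encoded mt-Atp8 fell by 2.35 (SE 0.60, adjusted p = 0.0439), from 27111 ± 10022 TPM (SD, n = 3) to 5107. The small nucleolar RNAs Rnu3b3 (167 TPM) and Snord14d (20.4 TPM) passed and were listed at 0 in all saline libraries. With size factors Wfdc18 differed by 4.27, Ltf by 3.26, Smim22 by 3.36, Hist1h2ah by 2.21 and mt-Atp8 by -1.95, and none of the 7 passed (adjusted p of 0.359 to 0.539). Without saline replicates 2 or 3 the adjusted p of Ltf was 1 and 0.518. Without saline replicates 1, 2 or 3 it was 0.634, 0.975 and 0.330 for Smim22 and 0.578, 0.676 and 0.341 for mt-Atp8, and without replicates 1 or 3 it was 0.451 and 0.827 for Hist1h2ah. Smim22 also lost the call without TIS sEV replicate 3 (0.384) and mt-Atp8 without TIS sEV replicate 1 (0.0509).

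Lower without passing were Lcn2 (-2.90), Spp1 (-2.26), mt-Nd4l (-2.18), S100a9, a calcium-binding protein of neutrophils (-2.26), and B3gnt2, a glycosyltransferase (-2.13), with adjusted p of 0.159 to 0.538. In all, 25 genes passed, 16 higher and 9 lower, of which 12 were small non-coding RNAs and 7 nuclear protein-coding genes, and 281 had an unadjusted p under 0.05. The Cont sEV library lay outside the saline range for 21 of the 25 and for 60.5% of all tested genes, where chance gives 50%. With size factors 1 gene passed, as lower, and 1539 had an unadjusted p under 0.05, while quantile normalization gave 2, both lower. Leaving out saline replicates 2 or 3 gave 11 and 13 calls, and leaving out TIS sEV replicate 2, which enters only through the spread, gave 197. Without TIS sEV replicate 2, with a pseudocount of 0.1 and with array weights, more calls were lower than higher. Rnu3b3, Snord14d and Wfdc18 passed in each of the 6 fits without 1 library, and the other 4 named genes that passed lost the call at least once.

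The lists of B and plasma cells, dendritic cells, antigen presentation and proliferation were higher in the Cont sEV tumour than in saline tumours. Medians relative to the median gene were 2.03 for B and plasma cells, with Igkc at 3.26 (SE 0.93), 1.08 for dendritic cells, with the chemokine Ccl17 at 1.92 (SE 0.78), 0.96 for epithelial tumour cells, in the library with Csn2 at 17.3 TPM, 0.87 for MHC class II, 0.72 for proliferation, with Mcm3 at 1.93 (SE 0.90), 0.70 for MHC class I, with the immunoproteasome subunit Psmb9 at 2.22 (SE 0.84), 0.61 for oxidative phosphorylation and 0.37 for interferon-stimulated genes. Neutrophils had a median of -1.45 and the mitochondrially encoded genes -0.24. Camera adjusted p of the 10 lists ran from 5.83e-12 to 0.0346, and the lowest adjusted p with an estimated correlation was 0.456. Leaving out saline replicate 2 gave medians of 0.58 for epithelial tumour cells, 0.58 for MHC class II and -0.46 for the mitochondrial genes, and leaving out saline replicate 3 gave 0.58 for interferon-stimulated genes and -0.43 for the mitochondrial genes, all still called (adjusted p of 0.000211 to 0.0160). With an estimated correlation the lowest adjusted p in these 2 fits was 0.664 and 0.734. In fry 0 lists passed, with a lowest adjusted p of 0.915 and 0 lists at an unadjusted p under 0.05. Adjusted over the list alone, 4 of 4 B and plasma cell genes passed as higher, 5 neutrophil genes as lower and Ltf as higher, 2 mitochondrial genes as lower and 1 macrophage gene as lower.

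Size factors ended the calls of MHC class II (median 0.93, adjusted p = 0.0526), B and plasma cells (1.835, adjusted p = 0.0953), epithelial tumour cells (0.95, adjusted p = 0.0953) and the mitochondrial list (-0.17, adjusted p = 0.610). Without saline replicate 1, 6 lists were called, the neutrophil median was -0.82 (adjusted p = 0.379), the mitochondrial median 0.19 (0.859), and interferon-stimulated genes and epithelial tumour cells were not called (0.0892 for both). Interferon-stimulated genes were not called without saline replicate 2 (0.0968), nor the mitochondrial list without TIS sEV replicate 1 (0.0898). Calls were gained without saline replicate 3 by fibroblasts (median from -0.020 to -0.34, adjusted p = 0.0186) and skeletal muscle (from 0.80 to 1.33, 0.000329), and without TIS sEV replicate 2, which enters only through the spread, by hypoxia and glycolysis (-0.42, 0.0355). The adjusted p of these calls was 0.734 to 0.922 with an estimated correlation. The fibroblast median was 0.37 without saline replicate 1 and 0.011 with size factors, not called in either. Among lists that did not pass, median and mean differed in sign for T cells (-0.096 and 0.071, test higher), cytotoxic and NK cells (0.047 and -0.10, test lower; median -0.023 without saline replicate 2) and TGF-beta targets (-0.18 and 0.0083, test lower). None of the 7 tested single genes passed, with Cdkn1a at 0.41 (SE 0.92), Mki67 at 0.38 (SE 0.91), Il6 at 0.29 (SE 0.58), Epcam at 0.58 (SE 0.90), Cd274 at 0.14 (SE 0.89), Ptprc at -0.32 (SE 0.75) and Adgre1 at -0.12 (SE 0.74; 0.018 with quantile normalization).

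**Figure D3:**
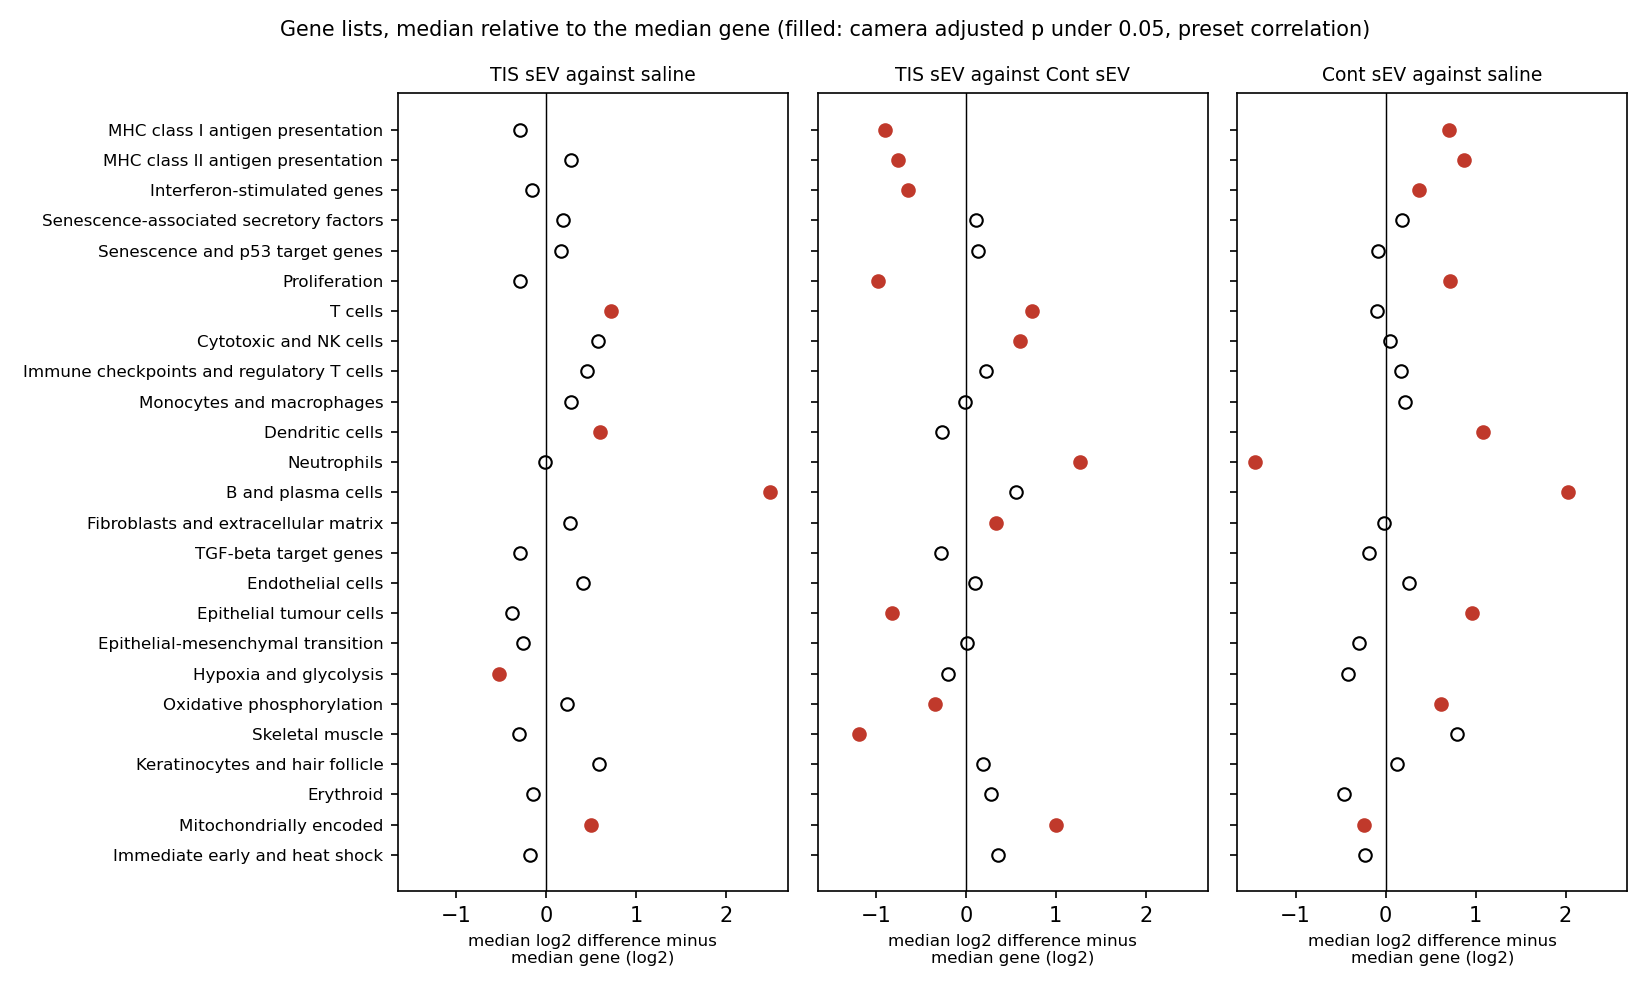
Median log2 difference of the members of 25 gene lists minus that of the median gene (horizontal axis) in the 3 comparisons, filled where camera at the preset correlation gave an adjusted p under 0.05. The B and plasma cell list lay at 2.49 in TIS sEV and 2.03 in Cont sEV against saline, and 0 lists passed with an estimated correlation in camera.

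The TIS sEV and Cont sEV differences from saline correlated across 12058 genes, which are not independent replicates, with Pearson's r = 0.547, Spearman's rho = 0.595 and a covariance of 0.179. Both use the same saline libraries, and unchanged groups simulated against them gave a mean r of 0.295 (-0.829 to 0.962) and a mean covariance of 0.0740 (-0.145 to 0.421) in 1000 draws. With genes drawn independently in 100 draws, the mean r was 0.355 and the mean covariance 0.178. The observed r and covariance lay inside the simulated ranges, and the covariance was close to that with independent genes. The same 4 genes were called higher and the same 4 lower in both comparisons. Unchanged groups simulated against the same saline libraries shared 4 or more higher calls in 12 of 100 draws and 4 or more lower calls in 10, and in 0 of 100 draws with independent genes. Lists drawn independently, which leave out the shared saline libraries, would share 0.056 and 0.015 genes. The 3 saline libraries cannot be split so that each part keeps 2, so the overlap may come from the shared controls.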

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

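The tests on nuclear coding genes alone, on size factors without TIS sEV replicate 2 and with each gene's own spread were chosen after the result was seen, and the other alternatives before. Over all alternatives, the values of named genes and list members kept direction and side of the threshold in 3369 cases, lost the call in 252, gained it in 180 and turned direction in 58. The values of called lists did so in 462, 96, 0 and 6. Values that were not called and stayed so count among the 3369, which is therefore no measure of how well the calls held. With size factors, quantile normalization, no filter or each gene's own spread, all 23 calls among the gene values were lost. Genes changed are given in the order TIS sEV against saline, TIS sEV against Cont sEV and Cont sEV against saline, where the test on TPM as deposited gave 62, 27 and 25, and 5, 12 and 10 lists. Except where named, the cause was not tested. Sequencing depth is unknown, so what it limits could not be measured.

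Size factors, which also changed the prior degrees of freedom from infinite to 3.04, gave 0, 1 and 1 genes (1781, 586 and 1539 at an unadjusted p under 0.05 in limma) and 6 lists for Cont sEV against saline, and quantile normalization 0, 1 and 2 genes (1755, 582 and 1377) and 7 lists for TIS sEV against Cont sEV. Nuclear coding genes alone gave 0, 0 and 0 genes (1717, 420 and 1717) and 9 lists against saline for TIS sEV, and with size factors 0, 0 and 0 genes (1705, 527 and 1476) and 6 lists for Cont sEV against saline. Size factors without TIS sEV replicate 2 gave 0, 1 and 1 genes (1493, 820 and 2402) and 11 lists for TIS sEV against saline. All 62 genes kept their sign with size factors. Each gene's own spread, on TPM as deposited, gave 0, 0 and 0 genes (389, 82 and 156), with 4 residual degrees of freedom.

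No filter gave 0, 246 and 233 genes (1230, 1033 and 1172 at an unadjusted p under 0.05). Of the 246, 243 were lower with TIS sEV than with Cont sEV, and of the 233, 230 were higher with Cont sEV than with saline. The filtered test shared 3 and 1 of these calls in the same direction. A mean TPM of at least 5 gave 33, 12 and 11 genes, with fewer genes tested. Robust moderation gave 32, 8 and 15 genes and an untrended prior 39, 12 and 16. Array weights, which did not converge, gave 7930, 1641 and 4186 genes and 17 lists for TIS sEV against saline. With saline and Cont sEV as 1 control group 9 lists were called for TIS sEV. An estimated inter-gene correlation gave 0, 0 and 0 lists.

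With the replicate number as a replicate block, 14, 5 and 9 genes and 5, 16 and 15 lists were called. Deviations of same-numbered saline and TIS sEV libraries from their group means correlated at -0.382, -0.00849 and 0.0797 across genes. Those of differently numbered libraries correlated at -0.336 to 0.368. These values show no sign of a pairing by number, but with 3 libraries in each group they cannot exclude it. With the replicate block, values against Cont sEV turned for Adgre1 (-0.49), Ptprc (-0.032), Tnc (0.52) and Mylpf (-0.55), and values of Cont sEV against saline for Adgre1 (0.42) and Cd274 (-0.32).

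Leaving out 1 library in turn gave 7 to 353, 10 to 103 and 11 to 197 genes, and 4 to 13, 11 to 12 and 6 to 12 lists. Arms left with fewer libraries, and the lone Cont sEV library, were assumed to vary like the others. The correlation of both changes from saline ran from 0.440 to 0.617. For TIS sEV against saline, the values relative to the median gene ran from -0.34 to 0.19 for Adgre1, -0.063 to 0.46 for Cd274, -0.15 to 0.30 for Fscn1, -0.30 to 0.34 for Itgax and -0.071 to 0.54 for Trac. For TIS sEV against Cont sEV they ran from -0.16 to 0.31 for Adgre1, -0.20 to 0.31 for Cd274, -0.0023 to 0.22 for Cdkn1a, -1.40 to 0.076 for H2-Eb1, -0.26 to 0.19 for Mylpf, -0.78 to 0.29 for Tnc and -0.020 to 0.50 for the fibroblast list. For Cont sEV against saline they ran from -0.39 to 0.15 for Adgre1 and -0.46 to 0.19 for the mitochondrial list.

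The other turned values are also relative to the median gene. For TIS sEV against saline, a pseudocount of 5 gave 0.0083 for Adgre1, 0.078 for Itgax and -0.12 for Fscn1, no filter gave -0.25 for Cd274, -0.20 for Trac and -0.42 for Fscn1, and array weights gave 0.23 for Itgax. For TIS sEV against Cont sEV, a pseudocount of 0.1 gave -0.11 for Ptprc and -0.12 for Mylpf, and a pseudocount of 5 gave -0.0080 for Cdkn1a. No filter gave -0.23 for Adgre1, -0.17 for Cd274, -0.18 for Cdkn1a, -0.25 for Ptprc, -0.27 for Mylpf, -0.017 for the fibroblast list and 0.015 for the skeletal muscle list. Size factors gave -0.10 for Ptprc and -0.089 for Mylpf, and quantile normalization -0.039 for Adgre1, -0.16 for Ptprc and -0.13 for Mylpf. Array weights gave -0.072 for Cd274, -0.15 for Cdkn1a, 0.062 for H2-Ab1, 0.032 for H2-Aa, 0.30 for H2-Eb1, -0.16 for Mylpf and 0.031 for the MHC class II list. Nuclear coding genes alone gave -0.11 for Ptprc and -0.14 for Mylpf, and with size factors -0.10 and -0.094. Size factors without TIS sEV replicate 2 gave -0.13 for Adgre1, 0.054 for H2-Eb1, 0.28 for Tnc and -0.22 for Mylpf. For Cont sEV against saline, no filter gave -0.14 for Cd274, quantile normalization 0.018 for Adgre1 and array weights 0.087 for the mitochondrial list.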

Other observations

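The tests of the Cont sEV library's range, of resident-type macrophages and of the chromosome 5 segment were set down before their values were seen, and the other tests and the mast cell lists were chosen after the result was seen. Mast cell proteases were higher in 2 of the 3 TIS sEV tumours. Mcpt1 was at 81.2, 2.39 and 82.7 TPM in the TIS sEV libraries and at 6.65, 7.82 and 0.545 in the saline libraries, a log2 difference of 3.22 relative to the median gene (SE 0.65, limma adjusted p = 0.0181), and Mcpt2 differed by 2.94 (SE 0.61, adjusted p = 0.0327). Both calls held without TIS sEV replicate 2 (differences of 4.33 and 4.01) and were lost without each of the 5 other libraries, with adjusted p of 0.0698 (saline replicate 1), 0.134 (saline 2), 0.879 (saline 3), 0.0866 (TIS sEV 1) and 0.546 (TIS sEV 3) for Mcpt1 and 0.202, 0.161, 0.879, 0.101 and 0.546 for Mcpt2. With each of these libraries left out in turn, the differences ran from 2.34 (saline 3) to 3.74 (saline 1) for Mcpt1, with 2.58 without TIS sEV 3, and from 2.31 (saline 3) to 3.30 (saline 2) for Mcpt2. Both calls were also lost with size factors (3.13 and 2.72, adjusted p = 0.338). A list of mast cell genes written after these were seen holds both. Of its 6 other tested members, 6 lay above the median gene (median 2.25), and in limma 0 passed and 5 had an unadjusted p under 0.05. Without TIS sEV replicate 2 the median was 2.61 and 5 passed, and with size factors it was 2.11 and 0 passed (4 at an unadjusted p under 0.05). The unadjusted camera p of these 6 genes with an estimated correlation was 0.0229, 0.0151 without TIS sEV replicate 2 and 0.18 with size factors. Hdc was the lowest of them at 0.19, with a fitted difference of -0.43. The members Kit, Fcer1a and Ms4a2 did not meet the filter and were not tested. Mean TPM with TIS sEV and with saline was 0.768 ± 0.647 and 0.956 ± 0.477 for Kit (SD, n = 3). It was 1.20 ± 1.12 and 0.422 ± 0.235 for Fcer1a, and 0.163 ± 0.123 and 0.146 ± 0.126 for Ms4a2.

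For the genes that differed between TIS sEV and saline, the 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 62 genes and 5 lists, and the highest other 315 genes and 17 lists, with 2 splits reaching 62 genes and 10 reaching 5 lists. On TPM as deposited, the split with 315 genes set saline replicate 1 with TIS sEV replicates 2 and 3, which points to a structure of the samples other than the treatment. These libraries had the lowest size factors of the 6 (1.02, 0.355 and 1.00, against 1.26 to 1.52). They also had the lowest shares of TPM in nuclear protein-coding genes (56.8%, 28.6% and 63.7%, against 64.8% to 74.7%). Without TIS sEV replicate 2, rich in ribosomal and small RNA, 41 of the 62 genes were called in the same direction, which argues against that library as the source of those calls, while for the other 21 it cannot be told apart from the treatment, since the group holds only 3 libraries. With size factors limma called 0 genes in each of the 10 splits, and 1781 genes had an unadjusted p under 0.05 in the real split, 1194 in the split with saline replicate 1 and TIS sEV replicates 2 and 3, and 168 to 406 in the others.

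The immunoglobulin genes did not rest on TIS sEV replicate 2 alone, since Igkc differed by 3.40 without it (adjusted p = 2.45e-13). Tissue rich in B cells, such as lymph node, would bring B cell surface genes, and the highest of these (Cd79b) reached 0.581 TPM in a TIS sEV library, which argues against it. Antibody-secreting cells, which carry little of these surface genes, may be the source, in response to the vesicles or by chance between samples. The Cont sEV tumour also held Igkc at 28.6 TPM, and with size factors Igkc did not pass (difference 4.59, adjusted p = 0.338, with a range of 2.45e-13 to 0.638 over the alternatives other than the array weights, which did not converge), where the prior had 3.04 degrees of freedom and each gene's own spread gained weight.

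The lists that differed between TIS sEV and Cont sEV may reflect the single Cont sEV tumour. Its list medians lay outside the range of the 6 other libraries for 6 of the 12 lists, exactly the bound set beforehand. For T cells it was outside by little, at -0.0957 against -0.0934 in saline replicate 2. The rule set beforehand asked for more than 6, so by that rule the library would not have counted as standing apart. A margin of 1 binomial SD around the bound, added after the value was seen, changed this outcome to open. The 12 lists were also chosen by their difference from this library. The library and the treatment cannot be told apart with 1 tumour. A larger share of tumour cells would lower all immune lists alike. In Cont sEV against saline, dendritic cell and neutrophil medians, a pair picked after the values were seen, lay 2.53 log2 units apart. The other immune medians were -0.096 for T cells, 0.047 for cytotoxic and NK cells, 0.22 for monocytes and macrophages and 2.03 for B and plasma cells. The lists were thus not all lower. The neutrophil median also ran from -0.61 to 0.72 among the saline libraries. With 1 Cont sEV tumour, these values cannot show whether a larger share of tumour cells contributed.

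Ccl8, Igf1, Cbr2 and Cd163 prompted the hypothesis of more resident-type macrophages in TIS sEV tumours. A list of other genes of these cells had a median of 1.06 relative to the median gene, with 10 of 10 tested members above it and 0 called by limma (1 at an unadjusted p under 0.05), a camera p of 5.10e-09 and a p of 0.0326 with an estimated correlation. The 4 other members stayed under 2 TPM in each library and were not tested, and the means with TIS sEV and with saline were 0.707 ± 0.974 and 0.861 ± 0.905 TPM for Lyve1, 0.194 ± 0.267 and 0.521 ± 0.769 for Cd209f, 0.316 ± 0.407 and 0.762 ± 0.739 for Vsig4 and 0.164 ± 0.135 and 0.0889 ± 0.0540 for Timd4 (SD, n = 3). The median was 1.23 with size factors (10 of 10 above, camera p = 0.000370, and p = 0.220 with an estimated correlation) and 0.83 without TIS sEV replicate 2 (8 of 10 above, camera p = 0.000159, and p = 0.168 with an estimated correlation). The bound set beforehand, a median of at least 0.5 and a camera p under 0.05, was met in these 3 settings, so the hypothesis may hold, but with an estimated correlation the p was under 0.05 only for all 7 libraries on TPM as deposited.

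Spp1, Ibsp and Dmp1, which lie between 104202613 and 104441050 on chromosome 5 (GRCm38), all fell in TIS sEV against saline, Ibsp by 2.45 (SE 0.59, adjusted p = 0.0111). Ibsp was not called without saline replicate 1 (adjusted p = 0.0996) or TIS sEV replicate 3 (0.388) or with size factors (-1.81, 0.429), it differed by -3.61 without saline replicate 2 (0.00779), and none of the 3 passed without saline replicate 3 (0.202 for Spp1, and 0.879 for Dmp1 and for Ibsp, at -1.37). A change in copy number of the whole segment would lower all neighbours by a like amount, but 14 other tested genes within 1 Mb had a median of -0.046 relative to the median gene, which argues against that hypothesis. On that scale Spp1, Ibsp and Dmp1 were at -1.94, -1.83 and -2.00. Of the 6 nearest neighbours, 5 also lay below the median gene without passing. Pkd2 was at -1.04, Hsd17b11 at -1.02, Gm42793, which overlaps Spp1, at -0.51, and Nudt9 and Sparcl1 at -0.44, while D930016D06Rik was at 0.011. The fitted differences of these 6 neighbours ran from -1.655 (Pkd2) to -0.61 (D930016D06Rik). In saline replicate 3, Dmp1 (92.5 TPM), Ibsp (45.9), Hsd17b11 (84.6) and Nudt9 (251) were higher than in each other library, so a change of a smaller segment, or in that library, was not excluded.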
